A study of Mus musculus with 9 samples.

How the data were processed

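The samples were nuclei and genomic DNA of E14Tg2a mouse embryonic stem cells. Per the labels' protocols, a biotinylated adaptor carrying a site for the enzyme MmeI was ligated to StyI-cut DNA, the ligated ends were captured on streptavidin and cut with MmeI to short tags of uniform length, and a second adaptor was added before gel purification and sequencing. Each StyI fragment is therefore counted by tags from its ends, so a count does not grow with fragment length as read coverage would, but short tags limit how many positions are told apart. Per the submitters' processing notes CASAVA 1.8.2 was used and the build is mm9. The aligner settings, the treatment of tags that match several places and the version of Repbase are not given in the sources used here.

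The deposited values are whole-number counts. A table per library gives, per the file contents, chromosome, start, end and count for adjoining StyI fragments, of which 3053721 were used (median length 539 bp). The repeat files give a Repbase name and a count, with names at 0 left out, and 312 names occurred in at least 1 library. Coordinates are those of the files, whose counting base is not stated, and bins are numbered from 1. The last interval of each of the 21 chromosomes had no second StyI site and was left out. Groups came from the sample titles. The titles D0, D12 and D21 of the inputs are not explained in the labels, and the 3 inputs were treated as 1 group.

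Fragment counts were summed into bins of 10 kb by fragment midpoint. HRS was compared with Loop, HRS with input and Loop with input by edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM scaling, filterByExpr with a minimum count of 10, and a Benjamini-Hochberg adjusted p of 0.05. Only the libraries of the groups compared entered each fit. Standard errors are the log2 ratio divided by the square root of the F statistic. Chromosome sums were tested on library totals without TMM, except in the length-corrected fits, which used a TMM factor over the chromosomes. Repeat counts were tested with TMM over the repeat table, and counts summed over classes, fixed by name, with the factors of the fit to names. Names were assigned by prefix, so the group of ERVK and IAP also holds LTRs of other retroviruses (RLTR names) and leaves out names such as MMERVK10C. Of these classes 6 were present, and 46 names belonged to none. No repeat name of a tRNA, snRNA, 7SL or rRNA class was in the tables. CPM values in the text are scaled by the library's total of the same table.

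The fits and all settings except those named as added were fixed before the data were examined. The rule for named items was fixed then too. It took the 10 regions with the largest log2 ratio of HRS over Loop in each direction among called bins with the same sign in all 3 replicate-numbered pairs and at least the median count, adjoining calls being merged. It took the 3 highest and 3 lowest chromosomes, up to 15 called repeat names in each direction, and the satellites in any case. The longest runs, the limit of 200 bp for short fragments, chromosomes 8 and 11, and repeat names other than satellites were chosen after their values were seen.

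The length correction, added later, divided fragments into 20 length classes. The expected count of a bin in a library was the sum over its fragments of the count pooled over the 9 libraries times that library's share of the class, and it entered the fit as an offset with a TMM factor. The other added settings were the letter in the repeat file names as a term or as a subset, chromosomes 8 and 11 left out, and both libraries of replicate 2 (repeats) or replicate 3 (fragments) left out. Alternatives fixed earlier were median-of-ratios factors, library totals, no filter, 100 kb bins, single fragments, an adjusted p of 0.01, all 9 libraries in 1 fit, the replicate number as a block, DESeq2 1.42.0, and each library left out in turn.

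The replicate numbers in the titles were taken to pair HRS with Loop on the fragment tables. The main fits nevertheless held no pairing term, as fixed before the data were examined. The pairs entered a fit only where the replicate number is named as a block. At 10 kb the deviations of same-numbered libraries from their group means correlated at 0.16, 0.101 and 0.224, each above the limit of 0.1 set for pairing. HRS replicate 2 correlated as well with Loop replicate 1 (0.114). Without chromosomes 8 and 11 the 3 values were 0.111, 0.082 and 0.16, of which 0.082 lies under that limit. In the repeat tables same-numbered libraries correlated at -0.43, -0.741 and -0.405, but each such pair has opposite letters, so these values do not show whether the numbers pair those tables. The block was run on them only as an alternative fixed earlier.

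The fits were tested on simulated counts with the real means and totals. For bins and repeat names the spread was the trend with mean count, not each one's own. Recovery may therefore be lower for names that vary more, such as the satellites. For chromosomes and classes each one's own spread was used. The changed bins were far fewer than the 93899 called in the data, so the shares recovered need not hold for the real fit. With 200 of 245700 bins changed between HRS and Loop, 13.4% of 1.5-fold, 71.6% of 2-fold and 97% of 4-fold changes were recovered, with 9 false calls. For HRS against input these shares were 26.9%, 73.1% and 100%, and for Loop against input 29.9%, 82.1% and 97%. With 40 of 289 repeat names changed between HRS and Loop, 75% of 2-fold and 100% of 4-fold changes were recovered, against input 90% and 100% for HRS and 95% and 100% for Loop. On 21 chromosomes 1 of 2 changes of 1.5-fold was recovered, and on 6 classes 1 of 2 changes of 8-fold. The fold sizes simulated for chromosomes and classes were altered between tries. Repeat names gave 1, 0 and 4 false calls for HRS against Loop, HRS against input and Loop against input. In counts that differed between libraries by fragment length alone, the uncorrected fit called 29877 bins between HRS and Loop and 75691 between Loop and input. The corrected fit called 0 in both. These counts were drawn from the same expected counts that the correction uses, so the 0 was set by the construction. It does not show that the correction removes all length effects from the real counts.

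The planned tests per gene and per gene list were not run, because the gene table at hand is of another build (GRCm38.p6) and positions were not converted. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and the R package data.table (version 1.17.8), with figures by matplotlib 3.10.9.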

Results

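High-salt recovered sequences (HRS) were mapped in E14Tg2a cells, a mouse embryonic stem cell line of 129P2 background that was grown with LIF. In this assay nuclei are extracted at high salt and the DNA is cut with the restriction enzyme StyI, after which the DNA kept with the insoluble nuclear material (the HRS fraction) is separated from the released DNA (the Loop fraction). The series holds 3 HRS libraries, 3 Loop libraries and 3 libraries of unfractionated input DNA, titled D0, D12 and D21. Each library has a table of counts over the StyI fragments of the mouse genome (mm9) and a table of counts over Repbase repeat names. The fragment tables summed to 51.5, 52.5 and 39.1 M counts for HRS replicates 1, 2 and 3. They summed to 62.9, 62.9 and 58.7 M for the Loop replicates and to 62.2, 56.6 and 55.2 M for the D0, D12 and D21 inputs. The repeat tables summed to between 1.68 and 2.67 M. Of 3053721 fragments, between 75.7% (HRS replicate 3) and 81.3% (Loop replicate 1) had a count, and the median fragment held 7 to 17 counts. No label says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

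The fractions differed in the length of the fragments they counted. Fragments of up to 200 bp held 51.7% ± 4.51 (SD, n = 3) of the counts in the Loop libraries, against 30.1% ± 1.68 (SD, n = 3) in the HRS libraries and 26.3% ± 0.72 (SD, n = 3) in input. Each Loop library lay above each HRS library, and each HRS library lay above each input library. The limit of 200 bp was chosen after the data were examined. The exact two-sided permutation p was 0.1 for each of the 3 comparisons, raw and adjusted, which is the smallest value that 3 libraries against 3 can give. The genome-wide comparisons were therefore also fitted with fragment length corrected, a setting chosen after the data were examined.

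**Figure D1:**
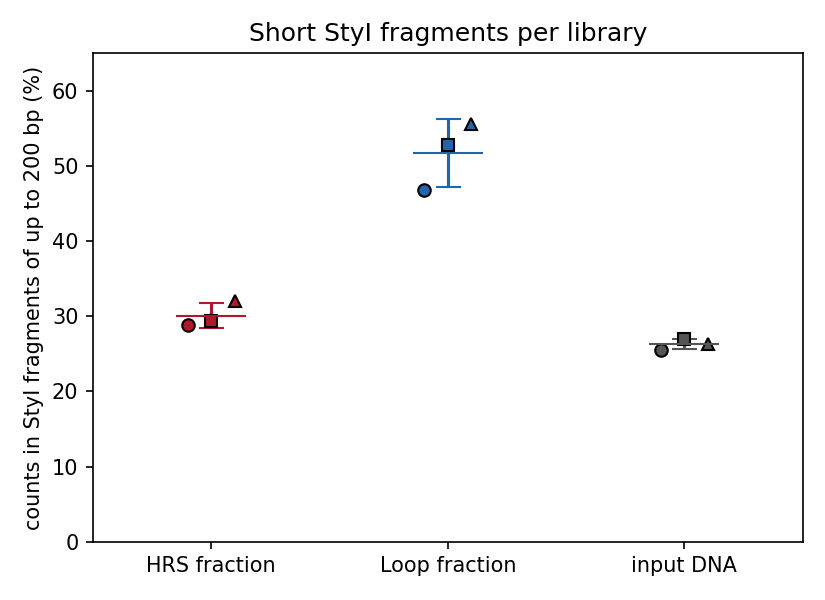
Percentage of counts (y axis) in StyI fragments of up to 200 bp for each library, by group (x axis). Circles, squares and triangles are replicates 1, 2 and 3 (D0, D12 and D21 for input), horizontal lines are means and error bars are SDs of 3 libraries. The Loop libraries sit between 46.8% and 55.6%, above all others.

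The first comparison asked which parts of the genome were retained with the HRS fraction rather than released with the Loop fraction. Counts were summed in bins of 10 kb. The longest stretch retained in HRS lay on chromosome 13, from 23340001 to 23870000, where all 53 adjacent bins were higher in HRS. This 530 kb stretch held 676 ± 49.8 CPM (counts scaled by the library total) in HRS, 153 ± 3.84 in Loop and 189 ± 5.98 in input (SD, n = 3 each), and its mean log2 ratio of HRS over Loop was 2.04. Further stretches followed on chromosome 10 (127970001 to 128370000, 400 kb, mean log2 ratio 1.13) and chromosome 4 (131730001 to 132110000, 380 kb, mean log2 ratio 1.22). The longest stretch higher in Loop was 410 kb on chromosome 15 (87780001 to 88190000), with a mean log2 ratio of -0.90. All these stretches are runs of calls made without the length correction.

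**Figure D2:**
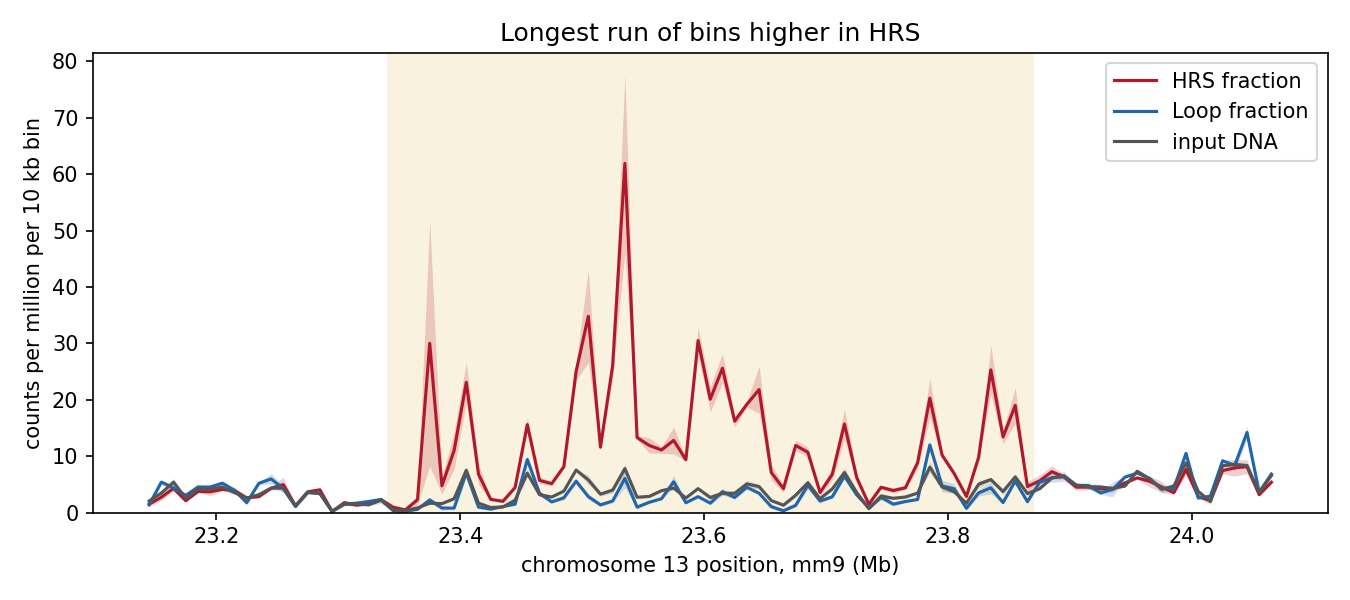
CPM in each 10 kb bin (y axis) along chromosome 13 in mm9 (x axis, Mb). Lines are group means of 3 libraries, bands are 1 SD, and the shaded part is the 530 kb run of bins higher in HRS, where HRS totals 676 CPM against 153 in Loop and 189 in input.

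The 10 regions with the strongest retention differed between HRS and Loop by 12.2-fold to 25-fold at their strongest bin, before the length correction. These bins ranged from 5 fragments with a mean length of 1974 bp (chromosome 18) to 19 with a mean of 502 bp (chromosome 7 at 87690001). The bin on chromosome 18 had only 32, 40 and 8 counts in the Loop replicates. The bin at 48630001 to 48640000 on chromosome 11, inside a run of 120 kb, held 22.7 ± 4.1 CPM in HRS and 0.895 ± 0.201 in Loop (SD, n = 3 each), a log2 ratio of 4.64 ± 0.22 (SE) with an adjusted p of 1.83e-10. On chromosome 2 the bin at 122200001 to 122210000 was 24.8-fold higher in HRS, with 28.8 ± 14.4 CPM against 1.16 ± 0.168. On chromosome 11 a second region peaked at 68920001 to 68930000 (20.9-fold, inside a run of 160 kb), where the log2 ratio was 4.38 and, without HRS replicate 3, 3.74. Chromosome 13 held a region around 21260001 to 21270000 (18.7-fold, also in a run of 160 kb), and the bin at 23390001 to 23400000 of the longest run was 13.6-fold higher. The others lay on chromosome 17 (80600001 to 80610000, 16.5-fold), chromosome 18 (35720001 to 35730000, 15.4-fold), chromosome 7 (52650001 to 52660000, 15.1-fold) and chromosome 4 (3750001 to 3760000, 12.2-fold). The bin at 87690001 to 87700000 on chromosome 7 was 24.9-fold higher and differed from the others in its make-up. A single fragment of 599 bp (87697319 to 87697918) held 97.5% of its counts, and the bin rose above input in both fractions, with 704 ± 235 CPM in HRS, 28.1 ± 10.7 in Loop and 8.89 ± 0.495 in input. The genes at these positions were not looked up, as no mm9 annotation was used here.

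The 10 strongest regions in the other direction were smaller in effect, from 3.11-fold to 4.37-fold higher in Loop. The largest ratio, at 86260001 to 86270000 on chromosome X, rested on Loop replicate 2, which held 787 counts there against 105 and 33 in the other Loop replicates, and without that library the log2 ratio was 0.01. The next was 55640001 to 55650000 on chromosome 2, with 28.8 ± 4.33 CPM in Loop and 8.25 ± 0.306 in HRS (SD, n = 3 each), a log2 ratio of -1.83 ± 0.19 (SE) with an adjusted p of 4.92e-07. A fragment of 59 bp held 81.5% of the counts of that bin. In 8 of the 10 regions the leading fragment was 48 to 156 bp long. The bins at 75340001 on chromosome 15 (3.27-fold) and 126650001 on chromosome 7 (3.24-fold) had leading fragments of 48 bp and 75 bp. With fragment length corrected, all 20 regions kept their direction and passed the threshold. The 10 regions higher in HRS then differed by 8.07-fold to 20.8-fold, while the bin on chromosome 2 at 55640001 differed by 1.52-fold.

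Across the genome 43857 of 245823 tested bins were higher in HRS and 50042 were higher in Loop. These calls are from the edgeR quasi-likelihood test without pairing, at a Benjamini-Hochberg adjusted p of 0.05. The retained bins differed by more: the median difference was 1.78-fold for bins higher in HRS and 1.56-fold for bins higher in Loop, and 15204 of the former but 4512 of the latter exceeded 2-fold. Of the bins higher in HRS 69.6% had a neighbour called in the same direction, against a mean of 32.8% when calls were shuffled within chromosomes. For bins higher in Loop these values were 57.9% and 37.3%. Runs of at least 10 bins numbered 602 for HRS and 209 for Loop. These figures are of uncorrected calls and were not recomputed with fragment length corrected. The shuffle did not keep any clustering of fragment length or StyI sites along the genome. It therefore cannot tell such clustering from that of the fractions. With the length correction 36751 bins were called higher in HRS and 20733 higher in Loop. The share of calls higher in HRS moved from 46.7% to 63.9%. Of the 93899 uncorrected calls, 43906 (46.8%) were made again in the same direction and 25 in the opposite one. The medians were then 1.64-fold and 1.41-fold, and 8535 bins higher in HRS and 408 higher in Loop exceeded 2-fold. With length correction and the replicate number as a block, 40686 and 26715 bins were called. With the letter A or B of the repeat file names as a term, 79121 bins were called.

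The comparison with input asked what each fraction gained or lost against unfractionated DNA. In HRS 37431 bins were higher and 22607 lower than in input, of 246935 tested. Gains were larger than losses, with a median of 1.62-fold against 1.42-fold and with 7565 gains but 451 losses over 2-fold. The named regions were chosen by HRS over Loop with these same HRS libraries, which favours such differences from input. The 10 regions most retained against Loop were higher in HRS than in input. They ranged from 4.44-fold on chromosome 7 (52650001 to 52660000) to 13.2-fold on chromosome 11 (68920001 to 68930000, log2 ratio 3.72, without HRS replicate 3 3.11). The single-fragment bin of chromosome 7 reached 87.4-fold. Of the 10 bins most enriched in Loop, 4 were lower in HRS than in input, by 1.36-fold to 1.83-fold, and the other 6 missed the threshold. Of the 4, those on chromosomes 10, 11 and 15 missed it when 1 of several libraries was left out, with adjusted p up to 0.184. Of the 6, those at 106130001 on chromosome 3 and 85530001 on chromosome 2 passed it with length corrected (adjusted p 0.013 and 0.0426) and without HRS replicate 2 (0.0271 and 0.0466). The bin on X also passed without HRS replicate 2 (log2 ratio -1.23, adjusted p 0.00874). The length correction left the comparison much as it was, with 38200 bins higher and 23993 lower and 56248 calls shared. Scaling on library totals moved the median log2 ratio from -0.03 to -0.16 and turned the split to 28934 higher and 43164 lower, so the balance of gains and losses is relative to the scaling. Without the D12 input 36457 bins were called and without the D21 input 33802.

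Most calls between Loop and input were lost once fragment length was corrected. Of 246731 tested bins 52979 were higher in Loop than in input and 44314 lower, with medians of 1.41-fold and 1.57-fold. After the length correction 657 bins were higher and 193 lower, and 548 of the first calls were shared. Of the 10 regions retained in HRS, 9 were depleted in Loop against input, by 1.53-fold to 3.64-fold. Of these, 4 passed the threshold after the length correction, on chromosomes 2, 7, 11 and 17, the largest at 80600001 to 80610000 on chromosome 17 (2.16-fold lower, adjusted p 0.00229). The other 5 were lower by 1.37-fold to 1.97-fold, with adjusted p of 0.0529, 0.0579, 0.0594, 0.0725 and 0.433. The single-fragment bin on chromosome 7 was 3.46-fold higher in Loop than in input and 5.43-fold higher after correction. The regions of both directions were chosen by HRS over Loop with these same Loop libraries, which favours such differences from input. All 10 regions higher in Loop than in HRS were higher in Loop than in input, by 1.74-fold to 4.82-fold. After the correction 2 of them passed the threshold, at 146500001 on chromosome 5 (2.14-fold) and at 86260001 on X, which missed it without Loop replicate 2 (uncorrected). Scaling on library totals moved the median log2 ratio from -0.02 to -0.15 and gave 33814 bins higher and 68289 lower.

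Whole chromosomes were compared by their share of the counts. The highest ratios of HRS over Loop were on Y (mean log2 ratio 0.15 ± 0.02), X (0.13 ± 0.03) and chromosome 10 (0.07 ± 0.01), and the lowest on chromosomes 12 (-0.07 ± 0.02), 9 (-0.05 ± 0.01) and 6 (-0.04 ± 0.04; SD, n = 3 replicate-numbered pairs for each). Chromosome X took 2.1% ± 0.082 of the counts in HRS, 1.91% ± 0.031 in Loop and 1.95% ± 0.023 in input. Among the autosomes and X it had the smallest share of tested bins called in either direction, 14.5% higher in HRS and 9.9% higher in Loop. Its bins held fewer counts, which limits calls there. X had 13767 tested bins with 2.1% of the HRS counts, while chromosome 6 had 14282 with 5.36%. No chromosome passed the threshold in the unpaired edgeR fit (0 of 21, with 4 at an unadjusted p under 0.05). DESeq2, also unpaired, called X and chromosome 17. In edgeR the adjusted p of X was 0.0699, and 0.00137 with the replicate number as a block. That block called 7 chromosomes, with Y, X, 10, 17 and 11 higher in HRS and 12 and 9 lower. With fragment length corrected, 5 were called (17 and 10 higher, 9, 12 and 18 lower) and X had a log2 ratio of 0.07 with an adjusted p of 0.0587. Adding the block to that correction called 11. Both fits also used a TMM factor in place of library totals, so the changes cannot be assigned to length alone.

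Replicate 3 of both fractions carried more of chromosomes 8, 11 and Y than any other library. Relative to input, the share of chromosome 8 was 1.18 in HRS replicate 3 and 1.21 in Loop replicate 3, and lay between 0.988 and 1.02 in the other 4 fraction libraries. The share of chromosome 11 was 1.32 and 1.21, against 1.004 to 1.061 in the other 4. The share of Y was 1.41 and 1.29, against 1.001 to 1.129 in the other 4. The inputs were not uniform either. The D0 input was above D12 and D21 on chromosome 8 (1.029 against 0.983 and 0.988) and chromosome 11 (1.047 against 0.980 and 0.973). On Y it was below them (0.932 against 0.990 and 1.078). The 95% Wilson intervals were at most ± 0.12% of the value for chromosomes 8 and 11 and ± 2.0% for Y, which cover counting error only. Without both replicate 3 fractions, 105265 bins and 10 chromosomes were called in HRS against Loop (4 higher and 6 lower), X among them. Without HRS replicate 3 alone, X and chromosome 10 were called.

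**Figure D3:**
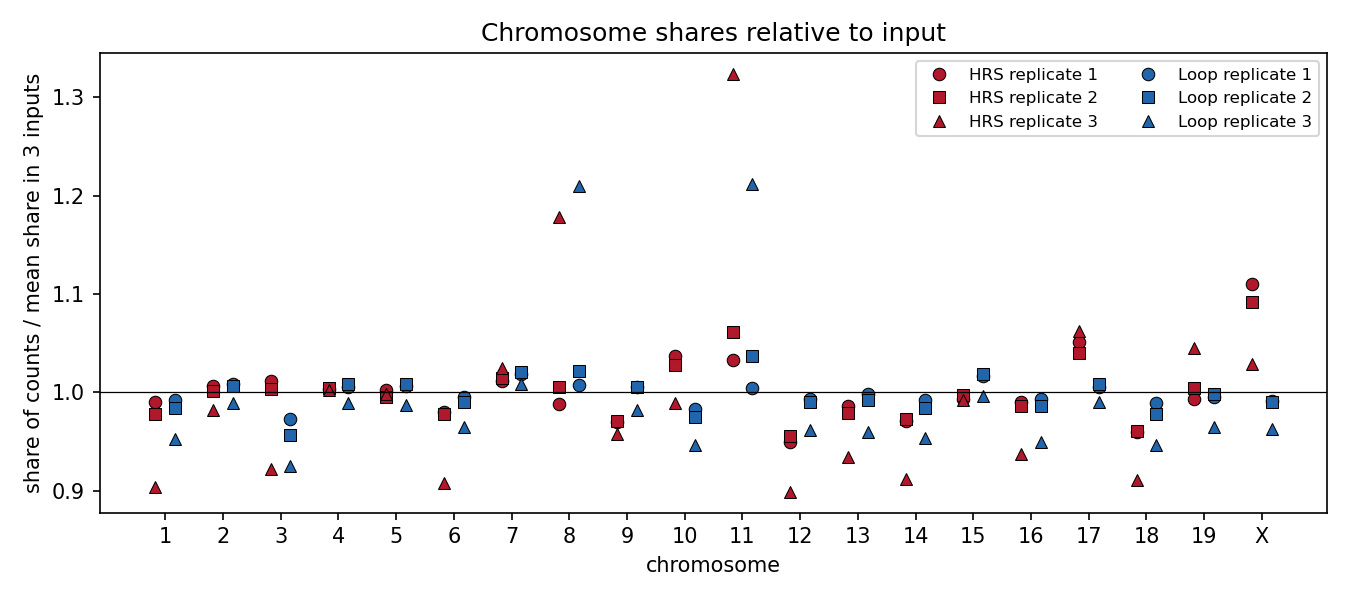
Share of counts per chromosome in each HRS (red) and Loop (blue) library divided by the mean share in the 3 inputs (y axis), by chromosome (x axis, Y left out). Circles, squares and triangles are replicates 1, 2 and 3. The triangles on chromosomes 8 and 11 lie between 1.18 and 1.32, and X in HRS lies between 1.03 and 1.11.

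The repeat tables addressed which repeated sequences each fraction held. By the labels as given, the satellite names varied within each fraction more than between fractions. GSAT_MM, the major satellite of mouse pericentromeres, took 44200, 6534 and 39443 CPM of the repeat tables labelled HRS replicate 1, 2 and 3, and 6925, 38196 and 2981 of those labelled Loop. The inputs held 8842 (D0), 11478 (D12) and 20912 (D21). The intervals of these shares (95% Wilson) were at most ± 2.23% of the value, which again covers counting error only. The log2 ratio of HRS over Loop was 0.90 ± 1.02 (SE, adjusted p 0.975) for GSAT_MM and 1.07 ± 0.91 (adjusted p 0.975) for SATMIN, the minor satellite of centromeres. Without the table labelled Loop replicate 2 these were 2.56 and 2.42 (adjusted p 0.663 each). No repeat name was called between HRS and Loop (0 of 289 in edgeR and in DESeq2, with 2 and 3 at an unadjusted p under 0.05). Of the 6 repeat classes present, 0 passed the threshold, with 0 at an unadjusted p under 0.05.

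The tables divided by the letter in their file names instead. HRS replicates 1 and 3 and Loop replicate 2 carry the letter A, and the other fraction tables the letter B. With fraction as a term, 94 of 289 names differed between letters, 38 higher in A and 56 higher in B, and GSAT_MM was higher in A by a log2 ratio of 2.76 ± 0.24 (SE). Within letter A and within letter B the comparison of HRS with Loop called 1 name each, RLTR6B_Mm, an LTR of an endogenous retrovirus. Each of these fits sets 2 tables against 1, the lone table being assumed to vary like the others. RLTR6B_Mm was lower in HRS within A (log2 ratio -0.98, the lone table being Loop replicate 2). It was higher within B (2.41), where the lone table, HRS replicate 2, held 11730 CPM. It is named here because it was the only call. With the letter as a term no name was called. A doubt about the replicate 2 tables led to a fit without both of them, chosen after the data were examined.

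**Figure D4:**
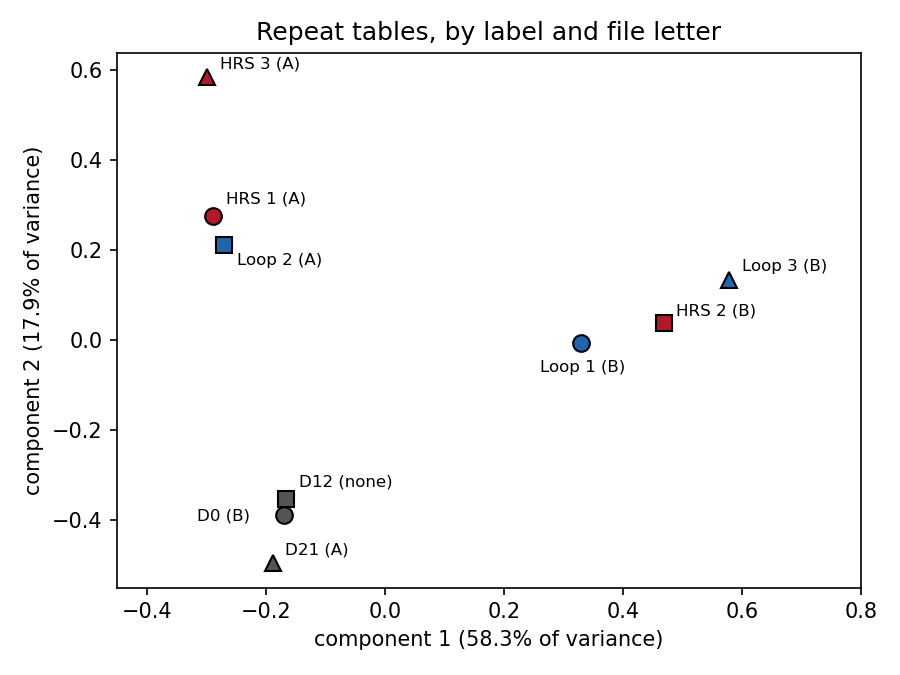
First (x axis, 58.3% of variance) and second (y axis, 17.9%) principal component of log2 CPM in the 9 repeat tables, HRS in red, Loop in blue and input in grey, with the letter of the file name in parentheses. HRS 1, HRS 3 and Loop 2 lie between -0.298 and -0.27 on the first component, and HRS 2, Loop 1 and Loop 3 between 0.33 and 0.579.

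Without the replicate 2 tables, both remaining HRS tables carry the letter A and both remaining Loop tables the letter B, so that fraction and letter cannot be told apart in this fit. The tables left out were those that lay apart from their fraction, so its calls restate the split by letter and are no separate evidence on HRS against Loop. The fit called 77 of 292 names, 32 higher and 45 lower in the 2 HRS tables. Both satellites were higher in them, GSAT_MM by a log2 ratio of 3.03 ± 0.25 (SE, adjusted p 8.48e-08) and SATMIN by 2.88 ± 0.21. Of 44 LINE-1 names tested in the 6 libraries, 14 were lower in these HRS tables and 0 higher, among them L1Lx_II (log2 ratio -1.11). The SINE names B1 and B2 were higher (0.61 and 0.49), and B1F missed the threshold. The group of names with the prefixes set for ERVK and IAP was mixed, with 23 names higher, such as MMETN (0.92), and 27 lower, such as RLTR2IAP_MM (-1.46) and IAPLTR3 (-1.74). These prefixes take in LTRs of other retroviruses and miss some ERVK names, so the counts are not those of ERVK and IAP. Of the names missed, MMERVK10C (0.50) and MMERVK9C_I (0.42) were higher and MMERVK9E_I (-0.39) lower. None of the 7 ERVL and MaLR names was called. As classes, satellites (log2 ratio 3.03), SINE B1 and SINE B2 were higher and LINE-1 was lower (-0.20), whereas with all tables each class had an adjusted p of 0.476. The names other than the satellites were chosen after their values were seen.

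Against input, no repeat name was called in HRS (0 of 291 in edgeR, with 54 at an unadjusted p under 0.05 and 28 called by DESeq2) or in Loop (0 of 288, with 75 and 37). Without the table labelled HRS replicate 2, 69 names were called, 37 higher and 32 lower than in input, and GSAT_MM (log2 ratio 1.63, adjusted p 0.00426) and SATMIN (1.701, adjusted p 0.000897) were among the higher. Without the table labelled Loop replicate 2, 115 were called, 71 higher and 44 lower, and GSAT_MM was then lower in Loop than in input by a log2 ratio of -1.40 (adjusted p 0.0283), as was SATMIN (-1.18, adjusted p 0.0112). The fraction tables left in these fits carry the letter A alone (HRS) or B alone (Loop), so that these calls cannot be assigned to the fraction. With all tables the log2 ratio of GSAT_MM over input was 1.17 in HRS and 0.26 in Loop.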

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

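The length correction, the letter subsets and the fits without replicate 2 or both replicate 3 libraries were chosen after seeing the data. Calls of bins stayed within 1.5 times of the reported count under the other scalings, no filter and all 9 libraries, and for HRS against Loop with the block (106133) and DESeq2 (86881), the latter not run on bins against input. For HRS against Loop they moved to 61579 at an adjusted p of 0.01, 57484 with length corrected, and, as other units are tested, 12575 with 100 kb bins and 398783 with single fragments. For HRS against input they moved to 33090 and 10653 (adjusted p 0.01, 100 kb bins), and for Loop against input to 54905, 6796 and, with length corrected, 850. Each library left out in turn gave 74375 to 97051 calls for HRS against Loop, 33802 to 67378 for HRS against input and 65723 to 98137 for Loop against input. Chromosomes went from 0 calls to 2 (DESeq2), 7 (replicate block) and 10 (without both replicate 3 fractions), and to 0 to 2 with a library left out. With length corrected, which for chromosomes also brought TMM scaling, they went to 5, and to 11 with the replicate block added. Repeat names of HRS against Loop went from 0 to 77 without the replicate 2 tables and 1 within letter A or within letter B (2 tables against 1), and stayed at 0 to 0 with any single table left out, as did the classes, where 4 were called without the replicate 2 tables. HRS against input went to 28 (DESeq2) and 0 to 69 with a table left out. Loop against input went to 37 (DESeq2), 27 (fragment table totals) and 0 to 115. Where no value or construction is named, the cause was not tested.

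Directions reversed for the bin at 86260001 on chromosome X, where HRS over Loop ranged from -3.525 to 0.006 with a library left out (the latter without Loop replicate 2) and HRS over input from -1.228 (without HRS replicate 2) to 0.557. HRS over input at 55640001 on chromosome 2, not called, ranged from -0.095 to 0.022 (without the D12 input) and was 0.018 without HRS replicate 1. With length corrected, Loop over input was -0.095 at 75340001 on chromosome 15 and -0.191 at 126650001 on chromosome 7. Loop over input ranged from -1.402 (without Loop replicate 2) to 0.747 for GSAT_MM and from -1.175 (likewise) to 0.595 for SATMIN, which was -0.029 without the D0 input. With fragment table totals these were -0.058 and -0.122, and of the classes by name prefix, none called, ERVK and IAP was 0.103, ERVL and MaLR 0.146 and LINE-1 0.103. ERVK and IAP ranged from -0.144 to 0.001 (without Loop replicate 3) with a table left out. With no mm9 annotation used, the alternatives of the gene tests were not run. Depth limits single fragments, whose median count was 7 to 17.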

Other observations

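The tests of StyI fragments per bin, of the letter and the exchange, of windows along chromosomes 8 and 11, of fragment length and of other splits were set down, with their bounds, only after their results had been seen.

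Retained DNA was poor in StyI sites in the uncorrected calls. Bins higher in HRS held a mean of 10.4 ± 3.86 StyI fragments (SD over bins), bins not called 11.5 ± 4.14, and bins higher in Loop 14.8 ± 4.58. The hypothesis that bins higher in HRS hold more StyI fragments than bins higher in Loop was not borne out. Their mean was the larger on 0 of 21 chromosomes. As the Loop libraries counted more short fragments, uncorrected calls may follow the spacing of StyI sites, so this is no independent test. With fragment length corrected, bins higher in HRS were no longer poor in sites. They held 12.2 ± 4.52, above bins not called (11.6 ± 4.29) on 16 of 21 chromosomes. Bins higher in Loop held 15.1 ± 4.48, and the HRS mean again exceeded theirs on 0 of 21 chromosomes. Bins are not independent replicates.

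Some features stood out in a single library, with replicate 2 of the other fraction next highest. The repeat RLTR6B_Mm took 11730 CPM of the table labelled HRS replicate 2, against 1424 to 3590 in the other 8 tables. The highest of those 8 was the table labelled Loop replicate 2. The fragment from 86263952 to 86265146 on chromosome X held 95.5% of the counts of its bin. There Loop replicate 2 had 787 counts and the other 5 fraction libraries 15 to 132. Of those 5, HRS replicate 2 had the most, 132 against 24 and 15 in HRS replicates 1 and 3. Both features were chosen after their values were seen.

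The repeat tables of the fractions lay apart by letter on their first component, by -0.745 (A minus B). In the fragment counts, 0 of 245823 bins were called for the letter (4551 at an unadjusted p under 0.05). The letters were read from the names of the repeat files. Whether the fragment counts come from the same sequencing run as the repeat counts is not known here. The bins argue against an effect of the letter carried by the whole library only if they do. Otherwise the bins cannot decide the question, as they would not carry the letter. A candidate explanation is that the repeat tables of replicate 2 were exchanged between HRS and Loop, which needs both to lie with the other fraction. They did, at distances of 0.014 and 0.023 from the mean of the other fraction against 0.762 and 0.724 from their own. That position is the split by letter which raised the question, so it is no separate test of an exchange. On the component of the bins all HRS fragment tables lay between 0.339 and 0.509 and all Loop fragment tables between -0.45 and -0.322. A step that treated the letters differently in counting repeats alone cannot be told apart from an exchange, as each letter has 1 input. On the first component of the repeat tables the D21 input (A) minus the D0 input (B) was -0.019. Single names went both ways. GSAT_MM was higher in D21 than in D0 (20912 against 8842 CPM), the direction of A over B in the fractions. RLTR2IAP_MM was also higher in D21 (5964 against 5082 CPM), opposite to its log2 ratio of A over B of -1.61. No biological explanation was tested.

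The excess of chromosomes 8 and 11 in both replicate 3 fractions ran along the whole chromosomes. In windows of 1 Mb, at least 96.6% of windows on each lay above the median of the other chromosomes in each fraction, and 100% did in Loop, where the median ratios of replicate 3 over replicates 1 and 2 were 1.22 ± 0.057 on chromosome 8 and 1.23 ± 0.05 on chromosome 11 (SD over windows). A trend with fragment length or StyI site density is argued against as the whole cause, since the lowest median ratio was still 1.191 after both were removed, when the highest of the other autosomes and X was 1.065 (chromosome 19 in HRS). Y, whose share over input was also high in both (1.411 in HRS and 1.292 in Loop), was left out of the windows and not tested. Extra copies of chromosomes 8 and 11 in part of the replicate 3 cells may account for their excess but remain a hypothesis. The windows test a gain along the chromosomes and not copy number, no input is labelled as from those cells, and no biological explanation was tested. The smaller rise of both chromosomes in the D0 input over the other inputs was not examined.

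For Loop against input the 97293 calls fell to 850 once length was corrected, in line with fragment length composition as the main source of those calls. For HRS against Loop 57484 bins were still called after the correction (43906 shared with the uncorrected calls), and for HRS against input 62193 (56248 shared). Length composition as the correction models it is thus argued against as the whole cause there. Length effects that the correction leaves are not excluded. Corrected calls of HRS against Loop that were higher in Loop still held more StyI fragments than bins not called (15.1 against 11.6). The correction bore more on bins higher in Loop, which went from 50042 to 20733, than on bins higher in HRS, which went from 43857 to 36751. The bin at 55640001 on chromosome 2 went from a log2 ratio of -1.83 ± 0.19 to -0.60 ± 0.14 (SE), and that at 48630001 on chromosome 11 from 4.64 ± 0.22 to 4.10 ± 0.20. Why the Loop libraries hold more short fragments was not tested, and a difference between fractions in the cells stays open.

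Libraries of 3 against 3 make 10 splits, too few for a share under 0.05. For the bins the real split alone (1 of 10) gave as many calls. It gave 93899, 60038 and 97293 calls for HRS against Loop, HRS against input and Loop against input. The highest of the other splits was 0 each time. Every other split mixes the groups, so a difference between them adds to the spread and few calls are left. The 0 is thus no measure of the calls made where no difference exists. For chromosomes and for repeat names against input the real count and the highest other were both 0, so that all 10 splits gave as many. For repeat names of HRS against Loop the real count was 0 and the highest other 114, and for classes 0 and 5, both from the split by letter, which points to a structure of the samples other than the fractions. Within a letter only 2 tables stand against 1, where 1 name was called in A and 1 in B, which decides nothing about the fractions. Of the splits, 4 part all 3 replicate pairs, as the real one does, and the split by letter is among them. The splits that part 1 pair gave 0 calls in each comparison of HRS with Loop.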
